A study of Mus musculus with 6 samples.

How the data were processed

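The samples were mouse bone marrow-derived macrophages, cells grown from marrow of male wildtype C57BL/6 mice into macrophages over 6 days. All 6 samples received conditioned medium, the culture supernatant of pancreatic acinar cells that had been stimulated with 200 nM caerulein for 5 h. Caerulein is a peptide that overstimulates acinar cells and is used to model acute pancreatitis. The medium was mixed 1:1 and left on the macrophages for 4 h. The 3 samples of the CM group received this medium alone. The 3 samples of the CM + 4OI group also received 200 µM 4-octyl itaconate (4OI), a cell-permeable ester of the macrophage metabolite itaconate. Per the labels, each group holds 3 biological replicates, numbered 1 to 3. Untreated macrophages and macrophages given 4OI without conditioned medium were not analysed here, so levels in both groups are levels under conditioned medium.

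RNA was sequenced as 150 nt paired-end reads on an Illumina NovaSeq instrument, per the labels' protocols. The deposited values are FPKM (fragments scaled to transcript length and to the mapped fragments of the library), calculated by the authors, with 1 column per sample and 55335 genes. The submitters' processing notes name FastQC 0.11.2 and the mouse build mm10. The aligner, the quantifier, the annotation and the strand setting are not given in the sources used here. Of the gene IDs, 55154 (99.7%) occur in GENCODE release M21, whose build GRCm38 is the same assembly as mm10, and coordinates are from that release. The file gives no symbol for 3225 genes, which stayed in the tests. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and the overlap is given for the named genes where it is above 5% of the exons. Genes of near-identical families, such as Ifit1bl1, Ifit3 and the Gbp genes, can share reads with their copies, and their values are uncertain to that extent.

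Fragment counts were not recovered, because the values are split between overlapping gene models and are not whole multiples of a single read throughout. The depth of each library was estimated from the smallest repeated step of FPKM times transcript length, over genes with a single transcript of at least 500 nt. It came to 21.7, 24.5 and 18.0 M fragments (M, mega) in CM replicates 1, 2 and 3 and to 25.3, 22.0 and 23.6 M in CM + 4OI replicates 1, 2 and 3. At these depths 1 FPKM of a transcript of 2000 nt stands for 36.0 fragments in the shallowest library and 50.6 in the deepest.

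The comparison of CM + 4OI with CM was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend and no further covariate. It covered the 10468 genes with a mean FPKM of at least 1 over the 6 libraries. Tests were two-sided, p-values were Benjamini-Hochberg adjusted, and a gene was called at an adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low FPKM. Ratios are of mean FPKM. Errors are SD over 3 replicates or the standard error of the log2 fold change (SE). Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

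Gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists that had at least 3 tested members. Of 27 lists fixed before the data were examined, 23 could be tested. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were run beside it. The groups, the main test, the alternatives listed first below, the lists and the rule for named genes were also fixed before the data were examined. The rule took the 10 called genes with the highest and the 10 with the lowest log2 fold change, with non-overlapping groups and established symbols. It also took the STING gene, Nfe2l2, Keap1, Acod1, Hmox1, Nqo1 and Ifnb1 whatever their result. For each list it took up to 4 called members with the largest absolute log2 fold change, or up to 2 with the highest mean FPKM where none was called. Other genes named in the text were chosen after their values were seen. Some genes that the rule took are not reported here.

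The groups share replicate numbers, and the labels do not say what a number marks. Over the tested genes, deviations from the group mean correlated between same-numbered samples with r = 0.344, 0.427 and 0.185 for numbers 1, 2 and 3. Each sample correlated best with its own number, and the highest correlation between different numbers was 0.0262. Same-numbered samples thus deviated alike, although deviations cancel out within a group, so these correlations are not independent of each other. A fit with the replicate number as a block was run as an alternative to the main test, which was fixed beforehand. The first principal component of log2(FPKM + 1), with 64.7% of the variance, separated the groups. The second, with 15.9%, separated number 2 from numbers 1 and 3 in both groups. Pearson correlations of log2(FPKM + 1) across genes were 0.985 to 0.991 within CM, 0.987 to 0.990 within CM + 4OI and 0.956 to 0.967 between the groups.

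The test was run on simulated data with 200 of 10468 genes changed. It recovered 37 of 66 genes (56.1%) changed by 0.5 on the log2 scale, 58 of 67 (86.6%) changed by 1 and 64 of 67 (95.5%) changed by 2. False calls were 10, or 5.92% of all calls. With no simulated effect, limma called 0 genes and camera 0 lists. The simulated genes were drawn independently and without a replicate effect. The simulation therefore cannot show how often camera calls a list whose members are correlated. In the data 32.5% of tested genes were called, far more than the share changed in the simulation. Benjamini-Hochberg adjustment is stricter where fewer genes change, so the simulated recovery need not hold for the data. The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean FPKM of at least 5, quantile normalization, median-of-ratios scaling, no variance trend, robust variance, the block, a log2 fold change of at least 1, and each library left out in turn. Chosen after seeing the data were the block with GC and length trends removed, IDs sharing a symbol summed, replicate 2 of both groups left out, and FPKM rescaled to equal sums outside the 10 highest genes.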

Results

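Gene expression was measured by RNA sequencing in mouse bone marrow-derived macrophages that had received conditioned medium from caerulein-stimulated pancreatic acinar cells. In 3 cultures the medium was given alone (CM), and in 3 it was given with 200 µM 4-octyl itaconate (CM + 4OI). The series title names inhibition of STING, the adaptor of cytosolic DNA sensing, and activation of NRF2, the transcription factor of the antioxidant response. The comparison therefore asks which transcripts differ when 4OI is added to macrophages exposed to medium of injured acinar cells. Estimated depths were 18.0 to 25.3 M fragments (M, mega) per library, and 10252 to 10658 genes per library reached 1 FPKM.

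With 4OI added, all 27 measured NRF2 target genes were higher, while 29 of 31 interferon-stimulated genes and 18 of 22 NF-kB-dependent inflammatory genes were lower. By camera these lists had adjusted p = 0.0178, 0.154 and 0.376 with an estimated correlation. By fry they had adjusted p = 4.23e-07, 1.60e-04 and 0.00611. The highest log2 fold change was that of Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis (ENSMUSG00000032350, chromosome 9, 77754535 to 77794485, plus strand, mm10). It rose 17.5-fold, from 11.8 ± 0.81 to 206 ± 15.4 FPKM (SD, n = 3 in each group here and below), a log2 fold change of 4.01 (SE 0.071, limma adjusted p = 3.66e-06). The lowest log2 fold change was that of Cxcl10, an interferon-induced chemokine (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889, minus strand), whose exons overlap Art3 on the other strand over 5.91% of their length. Cxcl10 fell from 433 ± 84.4 to 17.0 ± 7.46 FPKM, a log2 fold change of -4.65 (SE 0.28, adjusted p = 9.22e-05). Of 10468 genes tested with limma, 2020 were higher and 1385 lower with 4OI. With a log2 fold change of at least 1 in size, 111 were higher and 186 lower. Groups did not overlap in 3403 of the 3405 called genes and in 49.0% of all tested genes, where chance gives 10%. Median-of-ratios scaling gave 1394 higher and 1693 lower genes, so the share of calls that were higher was 59.3% as deposited and 45.2% with that scaling. The number of higher genes was 1311 without CM + 4OI replicate 2 and 1089 without replicate 2 of both groups.

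**Figure D1:**
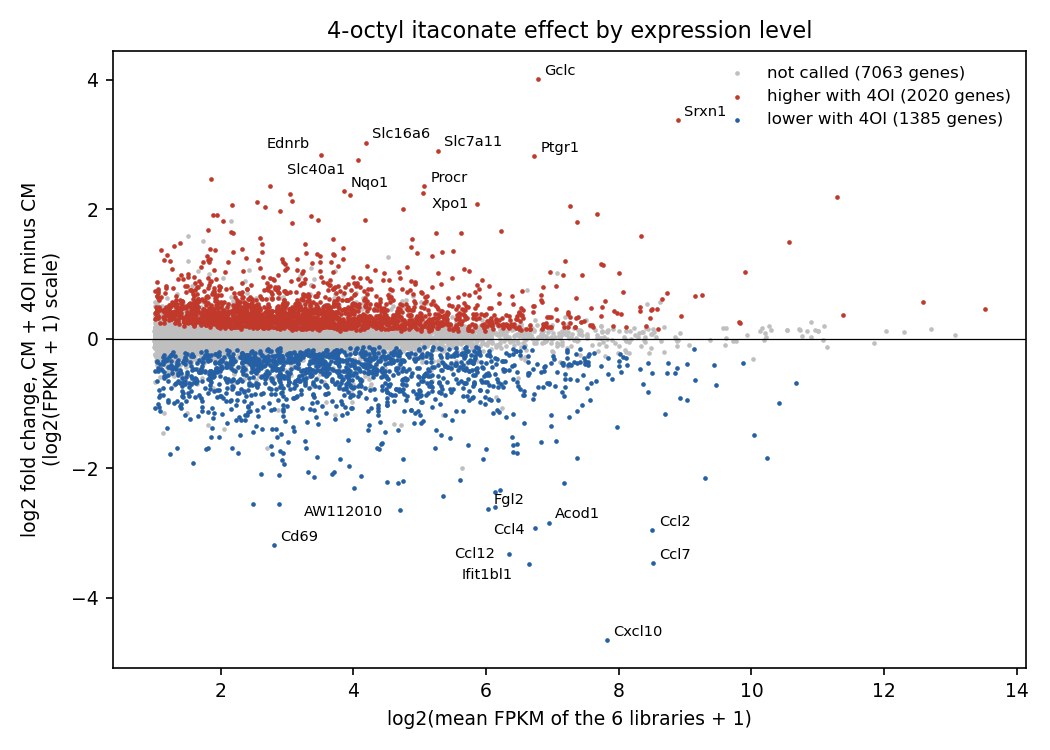
Log2 fold change of CM + 4OI against CM on the log2(FPKM + 1) scale (vertical axis) against log2 of the mean FPKM of the 6 libraries plus 1 (horizontal axis). Each point is a gene, red for the 2020 called higher, blue for the 1385 called lower and grey for the rest, and the named points are the 10 highest and 10 lowest changes under the rule for named genes.

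Among the other highest changes were Srxn1, which repairs oxidised peroxiredoxins (82.8 ± 8.61 to 869 ± 38.6 FPKM, 10.5-fold), and Slc7a11, the cystine importer that feeds glutathione synthesis (8.14 ± 0.784 to 67.3 ± 2.19 FPKM, 8.27-fold). Slc40a1, which encodes the iron exporter ferroportin, rose 8.58-fold from 3.29 ± 0.0449 to 28.2 ± 2.41 FPKM. Ednrb, an endothelin receptor, rose from 1.72 ± 0.295 to 19.0 ± 5.72 FPKM, and Procr, the endothelial protein C receptor, from 9.91 ± 0.738 to 55.01 ± 1.57 FPKM. Xpo1, the main nuclear exporter of proteins, rose 5.10-fold from 10.5 ± 0.191 to 53.6 ± 2.74 FPKM. Slc16a6, a member of the monocarboxylate transporter family, rose from 2.99 ± 0.374 to 31.6 ± 3.72 FPKM, with 21.5% of its exon length overlapping Amz2 on the other strand. The monocyte-attracting chemokines Ccl2, Ccl7 and Ccl12 were among the lowest changes. Ccl2 fell 7.36-fold from 639 ± 99.1 to 86.8 ± 42.2 FPKM, Ccl7 10.3-fold from 668 ± 165 to 65.0 ± 38.0 FPKM, and Ccl12 10.2-fold from 146 ± 30.3 to 14.3 ± 6.54 FPKM. Cd69, a leukocyte activation marker, fell from 11.6 ± 0.245 to 0.389 ± 0.106 FPKM. Fgl2, a fibrinogen-like protein, fell 6.45-fold from 111 ± 3.10 to 17.2 ± 1.22 FPKM. The interferon-response gene Ifit1bl1 fell 11.8-fold from 182 ± 6.25 to 15.4 ± 1.92 FPKM, and the long noncoding RNA AW112010 7.09-fold from 43.9 ± 5.67 to 6.19 ± 1.06 FPKM. The limma adjusted p of these genes lay between 3.66e-06 for Xpo1 and 0.00106 for Ccl7.

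**Figure D2:**
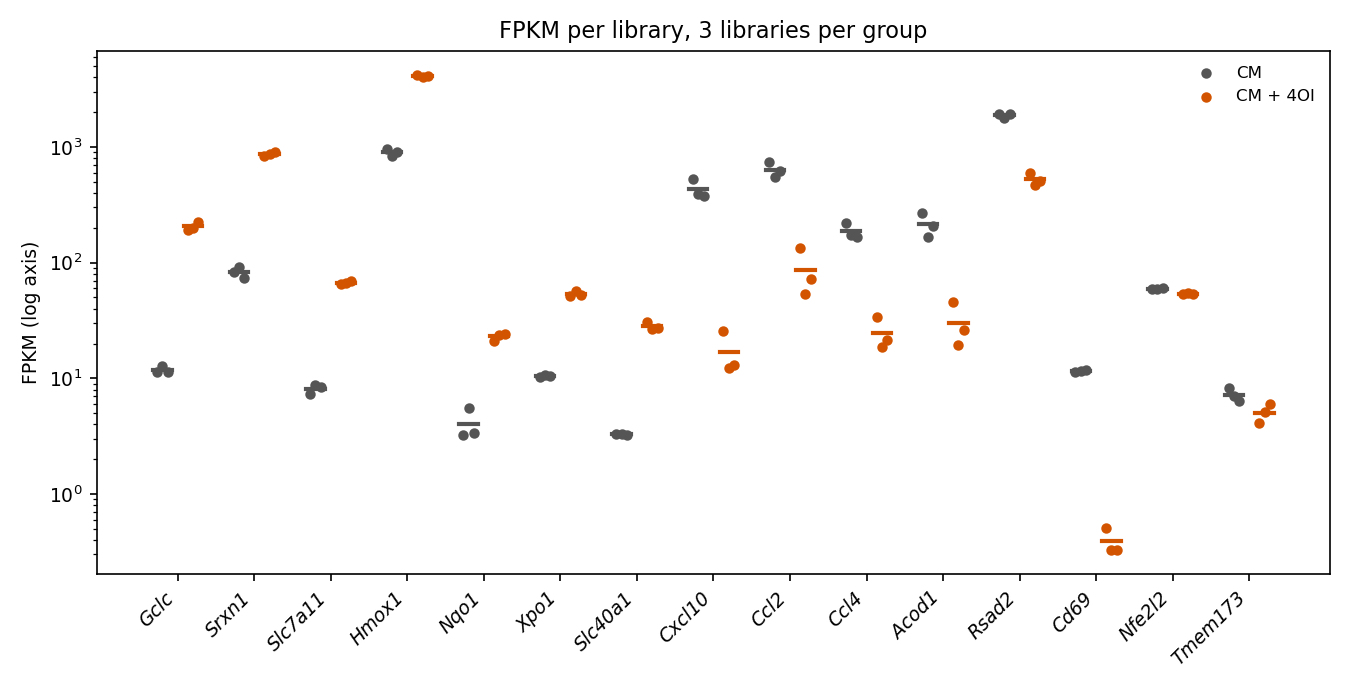
FPKM of 15 genes in each library on a log axis, with grey points for CM, orange points for CM + 4OI and bars at the group means (n = 3 per group). The groups lie apart for every gene drawn, by 17.5-fold in Gclc and by 1.43-fold in Tmem173, the gene of STING.

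All 27 NRF2 target genes on the list fixed beforehand were measured, and all 27 rose with 4OI. The number was also 27 when adjusted over the list alone. Their log2 fold changes ran from 0.31 to 4.01 with a median of 1.496, and 18 of them more than doubled in FPKM. Ptgr1, an NADPH-dependent reductase, rose 7.33-fold from 25.2 ± 2.24 to 185 ± 18.4 FPKM. Hmox1, the haem-degrading enzyme haem oxygenase 1, rose 4.57-fold from 901 ± 67.8 to 4121 ± 107 FPKM, and Nqo1, a quinone reductase, 5.68-fold from 4.05 ± 1.30 to 23.0 ± 1.62 FPKM. The list was higher by camera (adjusted p = 1.42e-18), and adjusted p = 0.0178 with an estimated correlation. The transcripts of NRF2 itself and of its repressor moved little. Nfe2l2, which encodes NRF2, fell 1.099-fold from 59.5 ± 0.529 to 54.1 ± 0.709 FPKM (limma adjusted p = 0.0249), and this call was lost in 8 of 19 alternatives, with adjusted p up to 0.454 under quantile normalization. Without CM replicate 2, CM replicate 3, or CM + 4OI replicate 1, 2 or 3, its adjusted p was 0.0646, 0.0745, 0.0653, 0.0613 and 0.0754. Keap1, which targets NRF2 for degradation, was at 16.9 ± 0.499 FPKM in CM and 16.3 ± 1.51 in CM + 4OI (limma adjusted p = 0.602), with 10.9% of its exon length overlapping Gm16754 on the other strand.

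Of 15 tested components of the cGAS-STING pathway, which senses cytosolic DNA, 7 fell, 0 rose and 8 were not called, with the same numbers adjusted over the list alone. The number that fell was 6 without CM replicate 1, 2 or 3, CM + 4OI replicate 1 or 2, or replicate 2 of both groups. It was 8 without CM + 4OI replicate 3. The list was lower by camera (adjusted p = 4.20e-04), but not with an estimated correlation (adjusted p = 0.141). Whether its fall is separate from that of the interferon-stimulated genes was not tested. Ikbke, a kinase that activates interferon regulatory factors, fell 3.25-fold from 21.6 ± 2.99 to 6.65 ± 0.669 FPKM. Ifi203 fell from 182 ± 1.47 to 108 ± 2.28 FPKM, the nucleic acid sensor Zbp1 from 69.0 ± 3.17 to 42.0 ± 3.06 FPKM, and Samhd1, a dNTP hydrolase, from 151 ± 3.32 to 93.2 ± 0.622 FPKM. The STING gene, listed under its older symbol Tmem173 (chromosome 18, 35733679 to 35740554), was at 7.22 ± 0.981 FPKM in CM and 5.06 ± 0.941 in CM + 4OI. Its log2 fold change of -0.45 (SE 0.14) had a limma adjusted p of 0.0482, which became 0.0905 with the replicate number as a block and was over 0.05 in 11 of 19 alternatives. Without CM replicate 1, 2 or 3 or CM + 4OI replicate 1 or 2, its adjusted p was 0.129, 0.0929, 0.0540, 0.0999 and 0.104. The gene of the sensor cGAS, listed as Mb21d1, was at 7.39 ± 0.203 and 6.49 ± 1.15 FPKM (limma adjusted p = 0.29), and Irf3, the transcription factor downstream of STING, at 5.60 ± 0.546 and 6.44 ± 0.487 FPKM (limma adjusted p = 0.15). Ifnb1, the interferon beta gene, lay under the filter at 0.474 ± 0.164 FPKM in CM and 0.105 ± 0.138 in CM + 4OI and was not tested.

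Interferon-stimulated genes were lower with 4OI in 29 of 31 tested members, also 29 adjusted over the list alone, and 0 rose. The members not called were Oas2 and Irf9. The median log2 fold change was -0.93. Cmpk2, a mitochondrial nucleotide kinase, fell 4.44-fold from 1033 ± 39.2 to 233 ± 23.0 FPKM, and its neighbour Rsad2, the antiviral protein viperin, 3.58-fold from 1881 ± 94.7 to 525 ± 60.8 FPKM. Gbp2, a guanylate-binding protein, fell 4.73-fold from 236 ± 6.82 to 49.9 ± 5.29 FPKM. The list was lower by camera (adjusted p = 2.95e-22), with adjusted p = 0.154 with an estimated correlation.

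NF-kB-dependent inflammatory genes fell in 18 of 22 tested members. Cxcl3, a neutrophil-attracting chemokine, rose, and 3 members were not called, while adjusted over the list alone 2 rose and 18 fell. Without CM replicate 2 also 2 rose. Beside Ccl2 and Ccl7, the macrophage inflammatory proteins Ccl4 and Ccl3 fell 7.65-fold, from 187 ± 28.5 to 24.5 ± 8.02 FPKM, and 5.25-fold, from 117 ± 22.8 to 22.2 ± 7.47 FPKM. Camera gave an adjusted p of 3.14e-09 for the list, and adjusted p = 0.376 with an estimated correlation. Among 11 inflammasome and pyroptosis genes 8 fell, Nlrc4 rose and 2 were not called (1 higher and 9 lower adjusted over the list alone). The inflammasome adaptor Pycard fell from 9.70 ± 0.157 to 4.21 ± 0.0301 FPKM, with 12.8% of its exon length overlapping Gm45205 on the other strand. The inflammatory caspase Casp4 fell from 14.4 ± 1.08 to 6.54 ± 0.421 FPKM, the cytokine Il18 from 29.2 ± 0.432 to 14.4 ± 1.01 FPKM and the DNA sensor Aim2 from 20.9 ± 0.360 to 10.8 ± 0.389 FPKM. This list was lower by camera (adjusted p = 1.32e-05), with adjusted p = 0.0887 with an estimated correlation.

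Antigen presentation genes fell in 7 of 15 tested members (7 adjusted over the list alone) and rose in 0. Cd40, a costimulatory receptor, fell 5.53-fold from 16.2 ± 3.14 to 2.94 ± 0.940 FPKM, the immunoproteasome subunit Psmb9 from 12.5 ± 0.727 to 6.50 ± 0.421 FPKM and Nlrc5, an activator of MHC class I genes, from 38.7 ± 2.63 to 24.3 ± 0.683 FPKM. The exons of Psmb9 overlap those of Tap1 on the other strand over 5.79% of their length. The list was lower by camera (adjusted p = 2.35e-04), with adjusted p = 0.519 with an estimated correlation. Genes of alternative activation also fell, in 5 of 10 tested members (5 adjusted over the list alone), with 0 higher. Arginase 1 (Arg1) fell 4.82-fold from 10.9 ± 2.38 to 2.25 ± 0.650 FPKM, the cytokine signalling inhibitor Socs1 3.92-fold from 6.24 ± 0.833 to 1.59 ± 0.418 FPKM and the cytokine Il10 3.39-fold from 4.17 ± 0.344 to 1.23 ± 0.440 FPKM. Camera gave an adjusted p of 0.0117, with adjusted p = 0.376 with an estimated correlation and 0.0765 at a mean FPKM of at least 5.

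Heat shock genes rose in 7 of 13 tested members and fell in 0 (8 and 0 adjusted over the list alone), and without CM replicate 3 the number that rose was 4. Hsph1, a large chaperone of the HSP70 class, rose from 8.56 ± 0.564 to 15.5 ± 1.01 FPKM, the cochaperone Bag3 from 26.0 ± 1.49 to 37.1 ± 1.55 FPKM and Hsp90aa1 from 75.7 ± 3.56 to 106 ± 9.82 FPKM. The list was higher by camera (adjusted p = 0.00957), with adjusted p = 0.376 with an estimated correlation. Hypoxia target genes fell in 5 of 12 tested members and rose in 1 (the same numbers adjusted over the list alone), or in 0 without replicate 2 of both groups. P4ha1, a prolyl hydroxylase of collagen, fell from 62.9 ± 4.75 to 38.7 ± 2.56 FPKM and the growth factor Vegfa from 58.7 ± 2.85 to 42.9 ± 3.51 FPKM. Camera gave an adjusted p of 0.0198, with adjusted p = 0.376 with an estimated correlation and 0.251 at a mean FPKM of at least 5.

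Acod1, whose enzyme makes itaconate (chromosome 14, 103046977 to 103056573), fell 7.07-fold from 215 ± 50.4 to 30.4 ± 13.5 FPKM (log2 fold change -2.84, SE 0.31, limma adjusted p = 9.25e-04). It was the single member of 21 tested genes of the TCA cycle and itaconate that fell, while 5 rose and 15 were not called (5 and 1 adjusted over the list alone). The number that rose was 3 without CM replicate 1 or 3 or CM + 4OI replicate 2 or 3, and 1 without replicate 2 of both groups. Idh1, an isocitrate dehydrogenase, rose from 31.5 ± 1.96 to 43.6 ± 3.61 FPKM. The glycolysis list split, with 6 of 17 tested members higher and 3 lower (7 and 5 adjusted over the list alone). Hexokinase 2 (Hk2) fell from 27.99 ± 3.30 to 15.3 ± 1.60 FPKM and Pkm, the pyruvate kinase, rose from 304 ± 9.44 to 412 ± 2.29 FPKM. Pkm shares 15.3% of its exon length with Gm49759 on the same strand. Of 11 genes of LXR targets and lipid efflux 3 rose and 4 fell, the same numbers adjusted over the list alone. Mylip, which marks the LDL receptor for degradation, rose 2.09-fold from 13.6 ± 2.19 to 28.4 ± 2.10 FPKM, while the cholesterol exporters Abca1 and Abcg1 fell from 52.96 ± 2.03 to 28.4 ± 1.85 FPKM and from 17.8 ± 1.76 to 9.28 ± 0.170 FPKM. Of 11 iron handling genes 3 rose, Slc40a1 among them, and 3 fell, the same numbers adjusted over the list alone. Without replicate 2 of both groups, 2 glycolysis genes and 1 gene of LXR targets rose, and 0 iron handling genes fell. Camera called none of these 4 lists, with adjusted p = 0.843 for the TCA cycle, 0.890 for glycolysis, 0.732 for LXR targets and 0.931 for iron handling. By fry, LXR targets were lower (adjusted p = 0.0211) and iron handling genes higher (adjusted p = 0.00155). Camera with an estimated correlation gave these 2 lists adjusted p = 0.919 and 0.974. The iron handling list had a median log2 fold change of 0.03 and a mean of 0.28, with Slc40a1 at 2.76.

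The remaining lists of cell processes were not called by camera. Of 18 genes of the integrated stress response 3 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.931), among them Slc3a2, the partner of cystine and amino acid transporters, from 128 ± 1.25 to 171 ± 11.2 FPKM. Without CM replicate 1 or CM + 4OI replicate 2 or 3 the numbers were 1 and 1, without CM replicate 2 or 3 also 1 fell, and without replicate 2 of both groups they were 1 and 0. Of 13 p53 target genes 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.890), but 0 fell without CM replicate 3, and 1 without CM replicate 1, CM replicate 2 or replicate 2 of both groups. The stress cytokine Gdf15 rose 2.65-fold from 6.63 ± 1.13 to 17.6 ± 2.65 FPKM. Of 21 cholesterol synthesis genes 2 rose and 1 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.911). These numbers were 1 and 0 without CM replicate 1 or 3 or CM + 4OI replicate 1 or 3, 1 and 1 without CM + 4OI replicate 2, and 4 and 0 without CM replicate 2. Of 20 lysosome and autophagy genes 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.962), and 2 fell without CM replicate 1. Gabarapl1, an autophagy protein, rose 2.08-fold from 34.0 ± 4.66 to 70.6 ± 4.35 FPKM, with 28.3% of its exon length overlapping 1700101I11Rik on the other strand. Of 17 cell cycle genes 2 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.568), with the replication helicase subunit Mcm6 from 17.8 ± 1.22 to 13.6 ± 0.600 FPKM (limma adjusted p = 0.0604 without replicate 2 of both groups). No cell cycle gene rose without CM + 4OI replicate 2, CM + 4OI replicate 3 or replicate 2 of both groups, and without CM replicate 1 or 3 the number was 1, with 2 lower without CM replicate 1. Of 13 mitochondrially encoded genes 1 rose and 0 fell (0 rose adjusted over the list alone, or without CM + 4OI replicate 2 or 3 or replicate 2 of both groups). That list had a camera adjusted p of 0.0528 and was called with the replicate number as a block, at 0.0137, but not with an estimated correlation (adjusted p = 0.974). It was also called without CM replicate 2, without CM replicate 3 and without CM + 4OI replicate 1, at 0.0400, 0.0345 and 0.0272. Median, mean and test differed in sign for p53 targets (median -0.06, mean 0.08, camera lower), the TCA cycle (median 0.05, mean -0.05, camera higher), LXR targets (median 0.02, mean -0.03, camera lower) and the lysosome list (median 0.02, mean 0.06, camera lower).

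**Figure D3:**
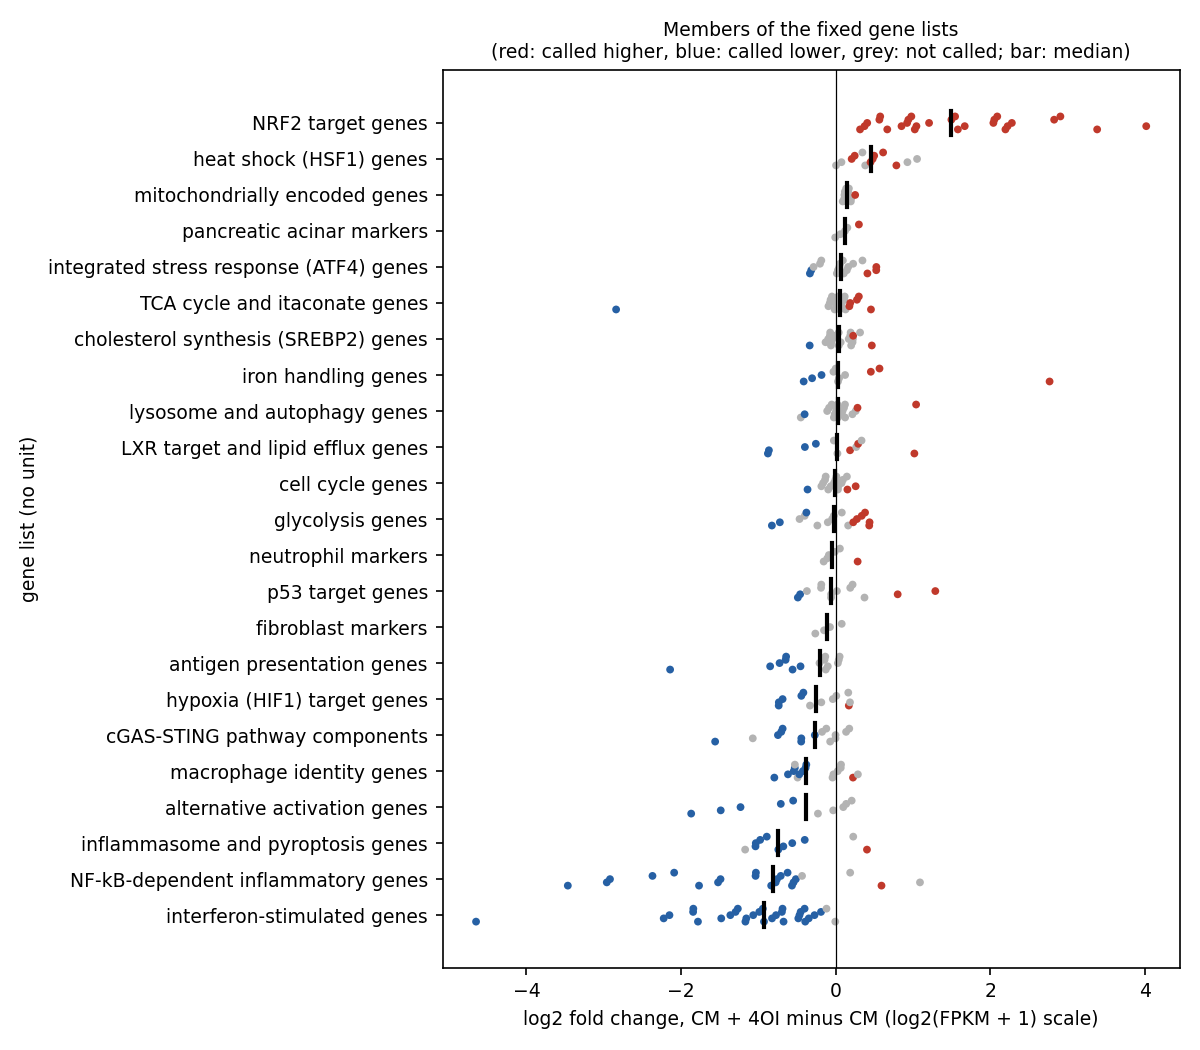
Log2 fold change of CM + 4OI against CM for each tested member of the 23 tested gene lists (horizontal axis, log2(FPKM + 1) scale), with the lists on the vertical axis ordered by their median, drawn as a black bar. Red and blue points are members called higher and lower and grey points were not called, and all 27 NRF2 targets lie above 0 while 29 of 31 interferon-stimulated genes are blue.

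Macrophage identity genes moved apart. Of 17 tested entries, with Itgam listed under 2 IDs, 8 fell, Trem2 rose and 8 were not called, the same numbers adjusted over the list alone. No member rose without CM + 4OI replicate 2 or 3 or replicate 2 of both groups, and 5 fell without the latter pair. The efferocytosis receptor Mertk fell from 23.3 ± 1.51 to 12.99 ± 0.972 FPKM, the scavenger receptor Msr1 from 186 ± 10.2 to 121 ± 12.7 FPKM and the Fc receptor Fcgr1 from 541 ± 22.1 to 375 ± 31.9 FPKM. Lysozyme (Lyz2) was at 8448 ± 293 and 8832 ± 243 FPKM, Cd68 at 855 ± 21.9 and 830 ± 19.3 FPKM and Adgre1, the F4/80 antigen, at 310 ± 15.3 and 316 ± 10.8 FPKM, and none of these 3 was called. The list was lower by camera (adjusted p = 0.00298), with adjusted p = 0.376 with an estimated correlation.

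Few markers of other cell types were called between the groups. Of 6 tested neutrophil markers 1 rose, also adjusted over the list alone, namely Mmp8 from 14.8 ± 1.13 to 18.2 ± 1.16 FPKM, a call lost in 6 of 19 alternatives, among them the fits without CM replicate 1 or 3 or CM + 4OI replicate 2 or 3, at 0.0607, 0.0604, 0.0844 and 0.0799 (camera adjusted p = 0.890). Of 5 tested pancreatic acinar markers 1 rose, Cela1, from 1.66 ± 0.0592 to 2.28 ± 0.266 FPKM, a call lost in 9 of 18 alternatives, among them each library left out except CM + 4OI replicate 2, with adjusted p from 0.0627 without CM replicate 3 to 0.0759 without CM + 4OI replicate 3 (camera adjusted p = 0.890, 1 adjusted over the list alone). The highest acinar marker, Ctrb1, was at 3.39 FPKM in CM and 3.50 in CM + 4OI. Of the dendritic cell markers 2 were tested, Itgax and Bst1, and 0 were called (limma adjusted p = 0.766 and 0.193). No lymphocyte, mast cell and basophil, or erythroid marker reached the filter, and their highest members were Cd79b at 0.530, Gata2 at 0.199 and Hba-a1 at 0.721 FPKM over the 6 libraries. The 4 tested fibroblast markers were not called (camera adjusted p = 0.890, 0 adjusted over the list alone), but they differed between replicate numbers. Col1a1, a collagen chain, was at 29.0 FPKM in CM replicate 2 against 4.69 and 2.93 in CM replicates 1 and 3. In CM + 4OI it was at 16.6 FPKM in replicate 2 against 4.23 and 4.30 in replicates 1 and 3.

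**Figure D4:**
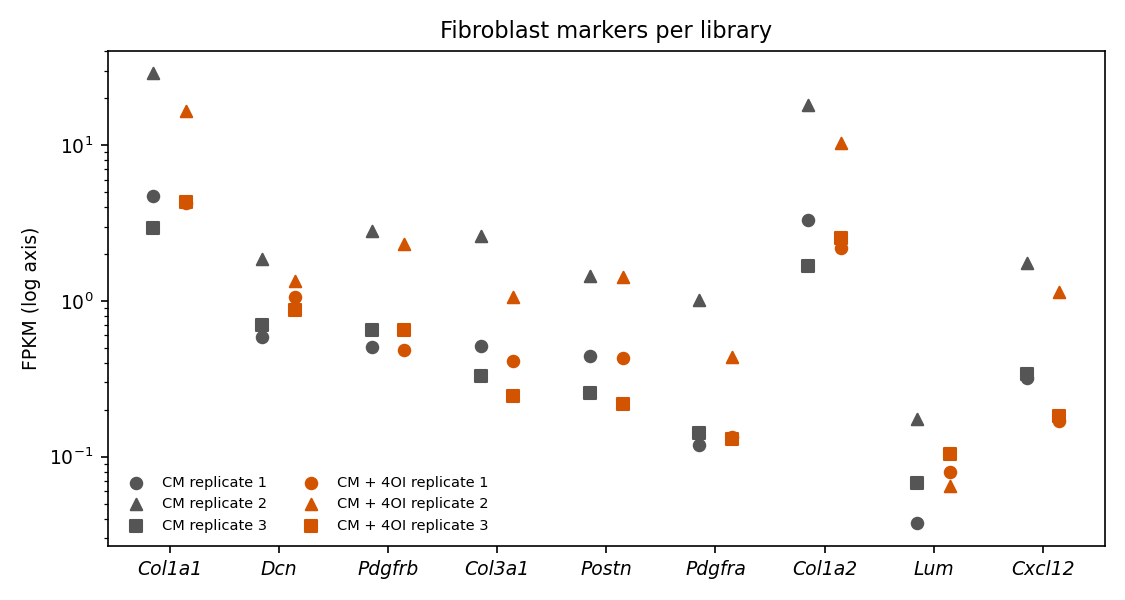
FPKM of the 9 fibroblast markers in each of the 6 libraries on a log axis, grey for CM and orange for CM + 4OI, with circles, triangles and squares for replicates 1, 2 and 3. In both groups the triangle is highest for 8 of the 9 markers, with Lum the exception.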

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

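Rescaling outside the 10 highest genes, GC and length trends with the block, summed IDs and the omission of replicate 2 of both groups were chosen after seeing the data. No gene called in the main test was called in the other direction in any alternative that refitted all genes. For the 94 named genes, 1664 of 1775 comparisons with an alternative kept the side of the threshold, and 111, in 22 genes, lost the call. Called genes changed sign in 0 comparisons, and 3 of the 5 uncalled genes, Itgax, Col1a1 and Col1a2, in 8. Leaving out each library in turn gave 1311 to 1855 higher genes, 1148 to 1246 lower genes and 10 to 11 called lists. The lowest higher count, 1311, was that without CM + 4OI replicate 2. The fits without 1 of the other libraries had as many samples and gave 1425 to 1855 higher genes. The 1089 higher genes without replicate 2 of both groups come from a fit with fewer samples than these. Requiring a log2 fold change of at least 1 in size left 111 higher and 186 lower genes, by construction. With an estimated correlation camera called 1 list, the NRF2 targets. The adjusted p was then 0.141 for cGAS-STING components, 0.154 for interferon-stimulated genes and 0.376 for NF-kB-dependent genes. Fry, which asks whether a list moves on balance in 1 direction, called 12 lists, among them the 10 called at the preset correlation. By fry the cGAS-STING components had adjusted p = 1.60e-04. The estimated correlation between members was 0.342 for the interferon, 0.525 for the NF-kB and 0.0112 for the cGAS-STING list against the preset 0.01. It was 0.00873 for the NRF2 targets and -0.0514 for the inflammasome list, yet their adjusted p also rose, to 0.0178 and 0.0887. For these 2 lists the values argue against a correlation above the preset one as the source. The cGAS-STING list had an estimate close to the preset value, yet its camera adjusted p went from 4.20e-04 to 0.141. A weaker value with an estimated correlation therefore cannot be read as a sign of correlated members alone. No other source of the weaker values was tested.

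The replicate number as a block gave 2336 higher and 1523 lower genes and 11 lists. Among the named genes and the tested lists it changed the call of Tmem173 (adjusted p = 0.0905, with a range of 0.0349 to 0.165 over all alternatives) and of the mitochondrially encoded list (0.0137), and no other call. Genes under the filter, such as Ifnb1, were not tested. The simulation, with 200 of 10468 genes changed, recovered 56.1% of changes of 0.5 on the log2 scale. How far depth limits either was not tested.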

Other observations

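The tests of the library scale, abundant genes and GC and length quartiles behind the balance of calls and of a lower share of macrophages were chosen after the result was seen, as were the genes named here outside the fixed lists. Families of genes that share a symbol stem were scanned for called members with Fisher's exact test, one-sided, in 622 tests over 311 families of at least 5 tested genes. Members of a family sit together or share regulators and are not independent. Lower genes were enriched in 10 families and higher genes in 0 at an adjusted p under 0.05. All 7 guanylate-binding proteins (Gbp), which attack membranes of intracellular pathogens, fell (adjusted p = 1.65e-04), with Gbp5 from 79.2 to 16.7 FPKM. All 9 tested Ccl chemokines fell (adjusted p = 4.46e-06). Of 9 Schlafen genes (Slfn) 7 fell (adjusted p = 0.00278), with Slfn4 from 135 to 39.0 FPKM, and of 12 Parp genes 8 fell (adjusted p = 0.00331) while Parp6 and Parp16 rose. Of 7 tested Ms4a membrane proteins 5 fell (adjusted p = 0.0456), with Ms4a4c from 119 to 19.1 FPKM. The other 5 families were Ifi, Il, Ifit, Oas and Casp. Translation initiation factors (Eif) were higher in 21 of 54 tested members and lower in 2, and proteasome ATPases (Psmc) were higher in 5 of 6 and lower in 0, with adjusted p of 0.0529 and 0.0756.

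Of 9 tested Toll-like receptor genes 5 were lower and 1 higher, and the family did not pass the scan for lower genes (adjusted p = 0.135). Tlr9, which senses DNA, fell from 11.2 ± 0.351 to 2.19 ± 0.285 FPKM (limma adjusted p = 2.06e-05), and Tlr2 from 123 ± 20.2 to 42.7 ± 10.5 FPKM (adjusted p = 0.00136), while Tlr13 rose from 111 to 153 FPKM. Genes outside the lists that rose included the scavenger receptor Cd36, from 633 ± 70.5 to 1284 ± 92.0 FPKM, glutamine synthetase (Glul), from 72.5 ± 1.76 to 256 ± 9.14 FPKM, and glutathione synthetase (Gss), from 1.999 ± 0.106 to 10.8 ± 1.51 FPKM. Ch25h, which makes 25-hydroxycholesterol, fell from 11.6 ± 4.92 to 1.06 ± 0.364 FPKM.

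More genes were called higher than lower, 59.3% of calls. With each library left out in turn, the share ran from 52.8% without CM + 4OI replicate 2 to 59.8% without CM replicate 2. Without replicate 2 of both groups it was 51.8%, so the excess of higher calls was then small. These fits have fewer samples than the main test, so a lower share cannot be put down to the omitted libraries alone. The 10 most abundant genes of each library held 16.6% to 17.3% of all FPKM in CM and 19.6% to 20.3% in CM + 4OI. That is at least 2.38 percentage points more, which lowers the share of FPKM left to other genes and on that scale argues against these 10 as the source. Shares of FPKM need not equal shares of fragments, to which each library was scaled. Summed FPKM was also higher with 4OI, at 296891 to 297391 per library against 288529 to 290959 in CM. Abundant genes ranked below these 10 were not tested. In the fit with the block the higher share lay between 58.9% and 62.1% in each quartile of GC content and of transcript length, which argues against a bias along either. Median-of-ratios scaling gave 45.2%, but it centres the median log2 fold change by construction (0.0043, from 0.064) and so decides nothing. A scale factor of each library and a rise of many transcripts with 4OI cannot be told apart, because no standard outside the scaling was analysed here.

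Macrophage identity genes were lower as a list by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.376). A lower share of macrophages would lower them alike and raise markers of other cells, but they differed among themselves beyond their errors (Cochran's Q over 17 entries was 330.1 on 16 degrees of freedom, against a 95% chi-square bound of 26.3 that treats genes as independent). The median log2 fold change of 17 markers of other cell types was 0.05 (95% bootstrap interval -0.09 to 0.12). In the fit with the block 9 identity genes were lower, and 9 with GC and length trends also removed, with a median log2 fold change of -0.39 before and -0.37 after, which argues against a GC content or transcript length bias as the whole source. The spread among identity genes argues against a lower share of macrophages as the whole source. No other explanation was tested.

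Replicate 2 of both groups stood apart. In replicate 2 of both groups 54 genes were over 2-fold above the other replicates, against 4 for replicate 1 and 7 for replicate 3. Genes over 2-fold below the others in both groups numbered 11 for replicate 2, 9 for replicate 1 and 3 for replicate 3. Of the 9 fibroblast markers, 8 were highest in replicate 2 of both groups. The levels of Sparc were 23.8 FPKM in CM replicate 2 against 4.90 and 5.23 and of Acta2 31.6 against 7.68 and 6.17. A GC content or transcript length bias is argued against by the median log2 excess of tested fibroblast markers, 1.65 with those trends removed as without. Erdr1 was lower in replicate 2, at 0.694 against 8.96 and 9.08 FPKM in CM and 1.13 against 13.03 and 13.19 in CM + 4OI. No other source of these differences was tested.

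Transcripts with short half-lives might fall fastest within 4 h. Among tested genes, 88.5% had an annotated 3' UTR, and an AU-rich octamer, a motif of unstable mRNAs, was present in 34.4% of lower, 34.8% of higher and 28.5% of uncalled genes. At fixed 3' UTR length and level the odds ratio of lower against uncalled genes was 1.24 (95% interval 1.07 to 1.43), and 1.89 (1.33 to 2.70) for genes lower by at least 1 on the log2 scale. For higher genes these were 1.096 (0.97 to 1.24) and 1.23 (0.77 to 1.98), intervals that overlap those of lower genes, and the difference between the directions was not tested. The interval of lower genes lay above 1, as short half-lives would give, but the octamer was about as frequent in higher as in lower genes. Untreated macrophages were not analysed here, so a fall within 4 h cannot be told apart from a smaller rise. Half-lives were not measured, and the values do not decide on a contribution of mRNA stability.

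With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split gave 2020 higher and 1385 lower genes, against at most 1 and 1 in the others, so 1 of 10 splits gave as many in each direction. Every other split mixes CM and CM + 4OI libraries, so the 4OI difference widens the spread within its groups. Part of that difference also remains between them. The other splits therefore do not show the gene or list counts of samples without an effect. For lists 4 of 10 splits, the real included, gave at least the 10 called, and the highest other gave 13. The 3 other splits that part all 3 same-numbered pairs gave 0 genes and at most 10 lists, and the remaining splits part 1 pair.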
